A study of Arabidopsis thaliana with 24 samples.

How the data were processed

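Total RNA from 80 mg of seed per sample was labelled with biotin from 400 ng, per the labels' protocols, and hybridised to 1-colour Affymetrix arrays. The data are the linear intensity values the authors deposited, with a column for each of 24 arrays. Per the submitters' processing notes, MAS5, RMA and Partek were used, with no versions. Which of them made the deposited values, and with what annotation, is not given in the sources used here. The upper quartiles of the arrays lay between 234.2 and 258 and their medians between 19.63 and 36.44, and how the values were scaled between arrays is not given in the sources used here. They were used as deposited, with cyclic loess scaling as an alternative. That scaling assumes that most transcripts keep their level, which the large changes between dry and imbibed seed may not meet, and it can move the balance of rising and falling probe sets. No background or detection call came with the values, so how far low intensities lie above background is not known here.

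Groups were taken from the sample titles, 8 groups of 3 arrays. The titles number the arrays of each group, and the labels do not say that they came from separate seed lots or plants, so p-values measure the spread between these samples, which may be technical. The 64 control probe sets entered no test, which left 22746 of 22810. Gene names came from a platform annotation updated by gene identifier through a table of assembly GCF_000001735.4 (TAIR10.1). In that annotation 13513 probe sets had 1 gene, 503 had several and were not named, and 8730 were not listed. Of the probe sets with 1 gene, 13436 were found in that assembly list, and 11933 had only a locus code as symbol. No genome sequence was used, and gene positions from that list served only to order genes along the chromosomes for the neighbourhood of *TIM17-1*.

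Values were transformed as log2(value + 16), and the offset understates changes of weak transcripts. In R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), 1 linear model of 8 group means was fitted over all 24 arrays with 16 residual degrees of freedom, followed by empirical Bayes moderation. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values of single genes are limma's. The contrasts were tim17-1 minus WT at each stage and averaged over the stages, each later stage minus the earlier one in each genotype, and the difference of those steps between genotypes. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so no p-value was taken from permutations, and other splits of the arrays served only to count the probe sets they called. The procedure was tested on simulated data in which 200 of 22746 probe sets were changed. Over 14 comparisons it recovered 31.2% to 96.9% of changes of 0.5 log2 units, 75% to 100% of 1 unit and 98.4% to 100% of 2 units, and at most 9.94% of calls were false. Changed probe sets were drawn from those with a mean over the median, and noise was independent with 1 SD per probe set at all stages. These shares need not hold for weak probe sets or dry seed. Deviations from the group mean (root mean square) were 0.116 in WT and 0.128 in tim17-1 at 0 h, against 0.0726 and 0.0795 at 48 h S.

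The model, the contrasts, the alternatives, 20 gene lists with 330 genes and the rule for naming genes were fixed before the data were examined. Of the 330 genes, 57 were measured by a probe set with 1 gene, and 10 lists had at least 3 such genes. The tested lists, with genes measured of those listed, were mitochondrial protein import (4 of 32), respiratory chain (10 of 24), alternative respiratory pathway (5 of 13), mitochondrial stress response (4 of 15) and gibberellin (4 of 23). The others were seed storage and oil body proteins (3 of 14), LEA and desiccation (6 of 17), oil mobilisation (4 of 21), heat shock (4 of 15) and cold response (4 of 16). Results for a list cover only its measured genes. Lists with 1 or 2 measured genes were not tested as sets: cell cycle (*PRL*), cell wall loosening (*EXPA8*, *XTH33*), circadian clock (*GI*), dormancy and abscisic acid (*SPT*), photosynthesis and greening (*LHCB4.1*, *PORB*) and seed coat (*BAN*, *AT3G50990*). The lists of the TIM17 family, light signalling, endosperm, and embryo axis and seedling tissue had 0 measured genes and were not analysed here. Where a gene had several probe sets the one with the highest mean was used.

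Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one. Adjustment was over 50 tests of genotype, 60 of steps and 30 of interactions. Counts of members are given over all probe sets and adjusted over the list alone. Among the lists fixed beforehand, median, mean and test differed in sign only where no call was made. These were seed storage at 0 h, the alternative respiratory pathway at 48 h S, oil mobilisation and cold response at 6 h SL, and the respiratory chain, alternative respiratory pathway and heat shock at 24 h SL. Over WT steps they were mitochondrial stress response and oil mobilisation in the first, and the alternative respiratory pathway, mitochondrial stress response and heat shock in the second. Over tim17-1 steps they were the alternative respiratory pathway and seed storage in the second. Among interactions they were import and the alternative respiratory pathway in the first, and cold response in the second. Another 10 lists were made after the data were examined and contain genes already seen, so they are not independent evidence. They hold genes of pollen, the mitochondrial genome, the plastid genome, nuclear photosynthesis, expansins and xyloglucan endotransglucosylases, the LEA family, small heat shock proteins, oleosins with caleosins and cupins, endoplasmic reticulum bodies, and pentatricopeptide repeat factors. Median, mean and test of these lists also differed in sign, mostly without a call. The exception was the expansin and xyloglucan endotransglucosylase list over the last step, with a median of -0.0033 in WT and -0.008 in tim17-1 and a higher call in each (camera, adjusted p = 0.0329 and 0.0365; adjusted p = 0.169 for each with an estimated correlation).

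Named genes were, at each stage, the 8 with the largest rise and the 8 with the largest fall among called probe sets with 1 gene and no overlap between the groups. For the average they were 10 each way with 1 sign at all stages, for each WT step 5 each way, for each interaction 5 each way, and up to 4 called members of each list. A subset of these is printed.

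Alternatives were an offset of 1, cyclic loess scaling, removal of the dimmest 30% of probe sets, a trended and robust prior, array weights, only the arrays of the groups compared, only probe sets with 1 gene, the replicate number as a block, an estimated correlation for lists, and leaving out each array. Quality was described by the 3' to 5' log2 differences of the actin, GAPDH and ubiquitin controls.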

Results

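Transcript levels were measured on 24 single-colour Affymetrix arrays of *Arabidopsis thaliana* seed, with 3 arrays in each of 8 groups. The groups crossed the wild type Col-0 (WT) and the mutant *Attim17-1* (tim17-1), named for TIM17, a channel subunit of the mitochondrial inner membrane translocase, with 4 stages of germination. The stages were dry seed (0 h), seed after 48 h of stratification in the dark at 4 °C (48 h S), and stratified seed moved to continuous light at 22 °C for 6 h (6 h SL) or 24 h (24 h SL). The labels give 15 days of ripening in one place and 14 days in another for the dry seed. They call WT dry seed freshly harvested and tim17-1 dry seed only dry, and 1 text field of the WT 6 h SL samples names stratification. Each stage therefore asked how the mutant differed from WT, each step between stages asked what changed as germination went on, and the interaction asked whether that change differed between genotypes.

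The table held 22746 tested probe sets as linear intensities. Between 39.3% and 44.5% of them lay over an intensity of 64 on each array. Replicate arrays differed by a root mean square of 0.108 to 0.244 log2 units, and the largest differences were those of tim17-1 0 h replicate 1 from the other two arrays of its group (0.244 and 0.24). The number of arrays, 3 per group, limits the precision of every value below. Changes are log2 differences of intensity + 16 with their standard error, and n = 3 arrays per group throughout. The first principal component, with 73.3% of the variance, followed the stages. On it WT lay at -163.1 to -161.9 and tim17-1 at -165.1 to -163.7 at 0 h, 12.34 to 13.74 and 13.66 to 15.15 at 48 h S, 54.45 to 59.08 and 45.57 to 49.98 at 6 h SL, and 98.19 to 101.2 and 93.4 to 94.06 at 24 h SL, so only the ranges at 48 h S overlapped. On the second component the genotypes lay apart at all 4 stages, with tim17-1 at the higher values.

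**Figure D1:**
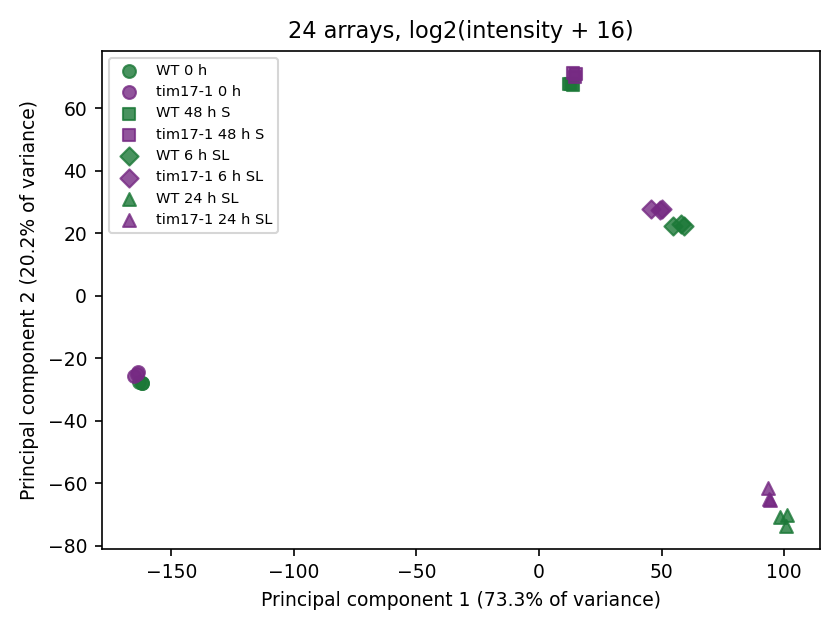
Each point is 1 of the 24 arrays placed by its first (x axis, 73.3% of variance) and second (y axis, 20.2% of variance) principal component of log2(intensity + 16), with stage as the symbol and genotype as the colour. The 4 stages lie apart, and the genotypes lie next to each other within a stage, with separate ranges on the second component at every stage and on the first at 0 h, 6 h SL and 24 h SL.

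The targeted gene *TIM17-1* and its homologs *TIM17-2* and *TIM17-3* are not analysed here, so the genotype labels were not checked by the target's own transcript.

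In dry seed, the dehydrin gene *COR47* fell in tim17-1, from an intensity of 121 ± 10.2 (SD, n = 3) in WT to 22.6 ± 18.8, a log2 change of -1.95 ± 0.235 (limma, adjusted p = 3.97e-05). *AT2G25450* fell most among the named genes, from 211 ± 68.5 to 23.4 ± 8.29 (-2.50 ± 0.163, adjusted p = 2.07e-08). *AT4G16190* (-2.04 ± 0.215), *CCL* (-2.02 ± 0.169) and *AT1G54410*, a dehydrin family gene (-1.85 ± 0.189), fell as well. *AT3G29120* rose from 16.7 ± 4.17 to 90.5 ± 15.8 (1.70 ± 0.105, adjusted p = 1.13e-08), and *AT3G29140* rose by 1.39 ± 0.095. *AT2G14060* (1.1 ± 0.147) and *AT5G05400* (0.87 ± 0.106) also rose.

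Of the 4 measured cold response genes, 2 fell in tim17-1 dry seed, *COR47* and *COR15A* (-1.79 ± 0.465, adjusted p = 0.0387), and the same count fell when adjusted over the list alone. *COR15B* (-0.03) and *LTI30* (0.01) did not pass. The list lay lower as a set (camera, adjusted p = 0.0187; adjusted p = 0.139 with an estimated correlation). The set call was also lost without WT 0 h replicate 1 (adjusted p = 0.06), and that of *COR15A* without WT 0 h replicate 1 (-1.54) or replicate 3 (-1.60), with array weights (-1.19) and with log2(value + 1) (-2.30). No member of the other 9 tested lists passed at this stage over all probe sets, and none of those lists was called. Adjusted over the list alone, 1 of 4 import genes and 1 of 4 gibberellin genes rose, and 1 of 10 respiratory chain genes and 1 of 4 oil mobilisation genes fell. The seed coat markers *BAN* (0.08 ± 0.0428, adjusted p = 0.417) and *AT3G50990* (0.03 ± 0.0288, adjusted p = 0.705) did not pass.

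Markers of pollen, taken from a list made after the data were examined, moved with the genes that were lower at 0 h: 14 of 21 measured markers fell, with a median change of -1.27. Among them were *AT3G62710* (-1.90 ± 0.183), *AT4G02250* (-1.86 ± 0.272) and *AT3G05610* (-1.84 ± 0.142), which are also among the 8 named genes with the largest falls. The 3' to 5' log2 difference of the ubiquitin control was -0.21 ± 0.0265 (SD, n = 3) in WT and -0.34 ± 0.0614 in tim17-1 dry seed, with no overlap between the arrays, which chance gives in 10% of such comparisons of 3 with 3. At 0 h, 300 probe sets were higher and 531 lower in tim17-1, 831 in all, of which 3 rose and 138 fell by at least 1 log2 unit. Without tim17-1 0 h replicate 1, 624 were higher and 552 lower, so the balance turned. With only the 6 arrays of this stage in the model 6 were higher and 33 lower, and with array weights 122 and 337.

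After 48 h of stratification, *AT1G72800* fell in tim17-1 from 180 ± 15.4 (SD, n = 3) to 8.23 ± 4.72, a change of -3.03 ± 0.154 (limma, adjusted p = 9.01e-09). The expansin gene *EXPA4* (-0.95 ± 0.12, adjusted p = 0.000493) and *CSLC04*, a glucan synthase gene of xyloglucan (-0.88 ± 0.152, adjusted p = 0.00778), also fell. *AT1G43590* (-1.27 ± 0.111) and *AT3G03320* (-0.74 ± 0.1) fell too. *AT3G29120* rose by 1.35 ± 0.105, *AT5G41670*, a 6-phosphogluconate dehydrogenase gene, by 0.62 ± 0.0927 (adjusted p = 0.0027), and *AT3G55690* by 0.52 ± 0.0824.

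Of 6 measured late embryogenesis abundant (LEA) and desiccation genes, whose proteins accumulate in drying seed, 2 fell at 48 h S and 3 when adjusted over the list alone. *AtLEA4-1* fell by 0.32 ± 0.0527 and *M17* by 0.45 ± 0.0934. The call of *M17* was lost without WT 48 h S replicate 1 (-0.42), 2 (-0.47) or 3 (-0.46) and without tim17-1 48 h S replicate 1 (-0.47) or 2 (-0.43). The list lay lower as a set (camera, adjusted p = 0.00203; adjusted p = 0.159 with an estimated correlation). No member of the other 9 tested lists passed over all probe sets. Of the 4 import genes, 1 rose and 1 fell when adjusted over the list alone. In all, 82 probe sets were higher and 198 lower, and cyclic loess scaling gave 109 and 143. The counts became 60 and 118 with only the arrays of this stage and 2242 and 1864 with array weights. They became 40 and 101, 28 and 73, and 53 and 153 without WT 48 h S replicate 1, 2 and 3, and 56 and 107, 53 and 82, and 221 and 264 without tim17-1 48 h S replicate 1, 2 and 3.

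After 6 h of light, the β-glucosidase gene *PYK10*, whose product is abundant in endoplasmic reticulum bodies, fell in tim17-1 from 144 ± 21.3 (SD, n = 3) to 54.4 ± 16.8 (-1.21 ± 0.134, limma, adjusted p = 0.000196). *NDB3*, an alternative NAD(P)H dehydrogenase of mitochondria, fell from 673 ± 13.2 to 386 ± 88.8 (-0.80 ± 0.138, adjusted p = 0.00625). *AT1G72800* (-1.72 ± 0.154), *AT5G45670* (-1.19 ± 0.119) and *AT4G26790* (-0.79 ± 0.0492) fell as well. *AT3G29120* rose by 1.70 ± 0.105, *AT5G66430* by 1.1 ± 0.138 and *AT2G43580* by 0.85 ± 0.122. *BGLU19*, another β-glucosidase gene, rose from 3558 ± 982 to 6461 ± 343 (0.89 ± 0.192, adjusted p = 0.0282). That call was lost without WT 6 h SL replicate 1 (0.68) or 3 (0.92) and without tim17-1 6 h SL replicate 1 (0.85), 2 (0.90) or 3 (0.93).

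Of the 6 LEA genes, 1 rose at 6 h SL, *M10* (0.39 ± 0.0678), and 2 rose when adjusted over the list alone. The list lay higher as a set (camera, adjusted p = 2.26e-06; adjusted p = 0.0573 with an estimated correlation). Of 4 gibberellin genes, 1 rose by both counts, the receptor gene *GID1A* (0.32 ± 0.0702, adjusted p = 0.0304), and the list lay higher (camera, adjusted p = 0.00905; adjusted p = 0.0573 with an estimated correlation). The *GID1A* call was lost without WT 6 h SL replicate 1 (0.31) or 3 (0.31) and without tim17-1 6 h SL replicate 2 (0.30) or 3 (0.26). Of 5 genes of the alternative respiratory pathway, 1 fell by both counts, *NDB3*, and its call was lost with log2(value + 1) (-0.83). The list itself was not called (adjusted p = 0.17). Of 10 respiratory chain genes, 1 fell by both counts, *SDH2-1* (-0.28 ± 0.0652, adjusted p = 0.0398), and the list was not called (adjusted p = 0.189). The *SDH2-1* call was lost with cyclic loess (-0.27), without WT 6 h SL replicate 2 (-0.26) or 3 (-0.25), and without tim17-1 6 h SL replicate 1 (-0.23) or 3 (-0.30).

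The 3' to 5' log2 difference of the GAPDH control was -0.16 ± 0.0443 (SD, n = 3) in WT and -0.01 ± 0.068 in tim17-1 at 6 h SL, with no overlap between the arrays, and it moved with the genes that were lower and those that were higher at this stage. In all, 116 probe sets were higher and 175 lower, and cyclic loess scaling gave 127 and 123. The counts became 311 and 536 with array weights and 87 and 106 with log2(value + 1), and limma called 0 with only the arrays of this stage, where 2165 lay at an unadjusted p under 0.05. They became 47 and 93 and 58 and 90 without WT 6 h SL replicate 1 and 3, and 50 and 91, 78 and 111, and 83 and 104 without tim17-1 6 h SL replicate 1, 2 and 3.

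After 24 h of light, *AT2G04770* rose in tim17-1 by 1.89 ± 0.128 (limma, adjusted p = 5.75e-08) and *BGLU19* rose from 270 ± 98 (SD, n = 3) to 646 ± 74.1 (1.26 ± 0.192, adjusted p = 0.00051). *AT3G29120* (1.24 ± 0.105), *AT1G47980* (0.98 ± 0.143) and *AT1G22600* (0.91 ± 0.123) also rose. *AT2G42220* fell from 110 ± 6.28 to 36.4 ± 6.07 (-1.26 ± 0.0518, adjusted p = 6.52e-11). *AT5G42760* (-1.41 ± 0.126), *AT5G26260* (-1.16 ± 0.107) and the peroxidase gene *AT5G64100* (-1.16 ± 0.204) fell too. *PORB*, which makes chlorophyllide in the light, fell by 0.63 ± 0.0698 (adjusted p = 1.73e-05), while *LHCB4.1*, a light-harvesting protein gene, did not pass (-0.25 ± 0.0723, adjusted p = 0.0631).

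Of the 6 LEA genes, 4 rose at 24 h SL and 5 when adjusted over the list alone. *LEA4-5* rose by 0.50 ± 0.0963, *M10* by 0.40 ± 0.0678, *AtLEA4-1* by 0.39 ± 0.0527 and *AT3G15670* by 0.42 ± 0.111. The call of *AT3G15670* was lost without WT 24 h SL replicate 1 (0.39) or 2 (0.30), without tim17-1 24 h SL replicate 1 (0.42), 2 (0.42) or 3 (0.44), and with array weights (0.32). The list lay higher as a set (camera, adjusted p = 1.78e-06; adjusted p = 0.0573 with an estimated correlation). Of 4 mitochondrial stress response genes, 1 fell, the glutathione transferase gene *GSTU25* (-1.08 ± 0.19), and 2 fell when adjusted over the list alone. That list lay lower (camera, adjusted p = 0.0276; adjusted p = 0.11 with an estimated correlation), but not without WT 24 h SL replicate 3 (adjusted p = 0.0758) or tim17-1 24 h SL replicate 1 (adjusted p = 0.0505).

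None of the 4 oil mobilisation genes passed over all probe sets at 24 h SL and 1 rose when adjusted over the list alone, with the list higher (camera, adjusted p = 0.0287; adjusted p = 0.176 with an estimated correlation; adjusted p = 0.0564 with cyclic loess). That call was also lost without WT 24 h SL replicate 1 (adjusted p = 0.156) or 3 (adjusted p = 0.063) and without tim17-1 24 h SL replicate 1 (adjusted p = 0.0505) or 3 (adjusted p = 0.143). Of 4 cold response genes, 1 rose by both counts, the dehydrin gene *LTI30* (0.61 ± 0.13, adjusted p = 0.0094), but not without WT 24 h SL replicate 2 (0.52) or tim17-1 24 h SL replicate 1 (0.56). That list was not called (adjusted p = 0.263), nor were the heat shock genes (adjusted p = 0.774) or the seed storage and oil body genes (adjusted p = 0.254; adjusted p = 0.00275 without WT 24 h SL replicate 3). The respiratory chain list was not called (adjusted p = 0.933), and its median (0.04) differed in sign from its mean (-0.0032) and its test. The median of the heat shock genes (-0.0058) differed in sign from their mean (0.07) and test. Adjusted over the list alone, 1 gibberellin gene and 1 heat shock gene rose and 1 respiratory chain gene fell. In all, 362 probe sets were higher and 621 lower, 983 in total, and cyclic loess scaling gave 254 and 757. With only the arrays of this stage limma called 4, all lower. The counts became 186 and 544 without WT 24 h SL replicate 1, and 214 and 433 and 225 and 542 without tim17-1 24 h SL replicate 1 and 3.

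**Figure D2:**
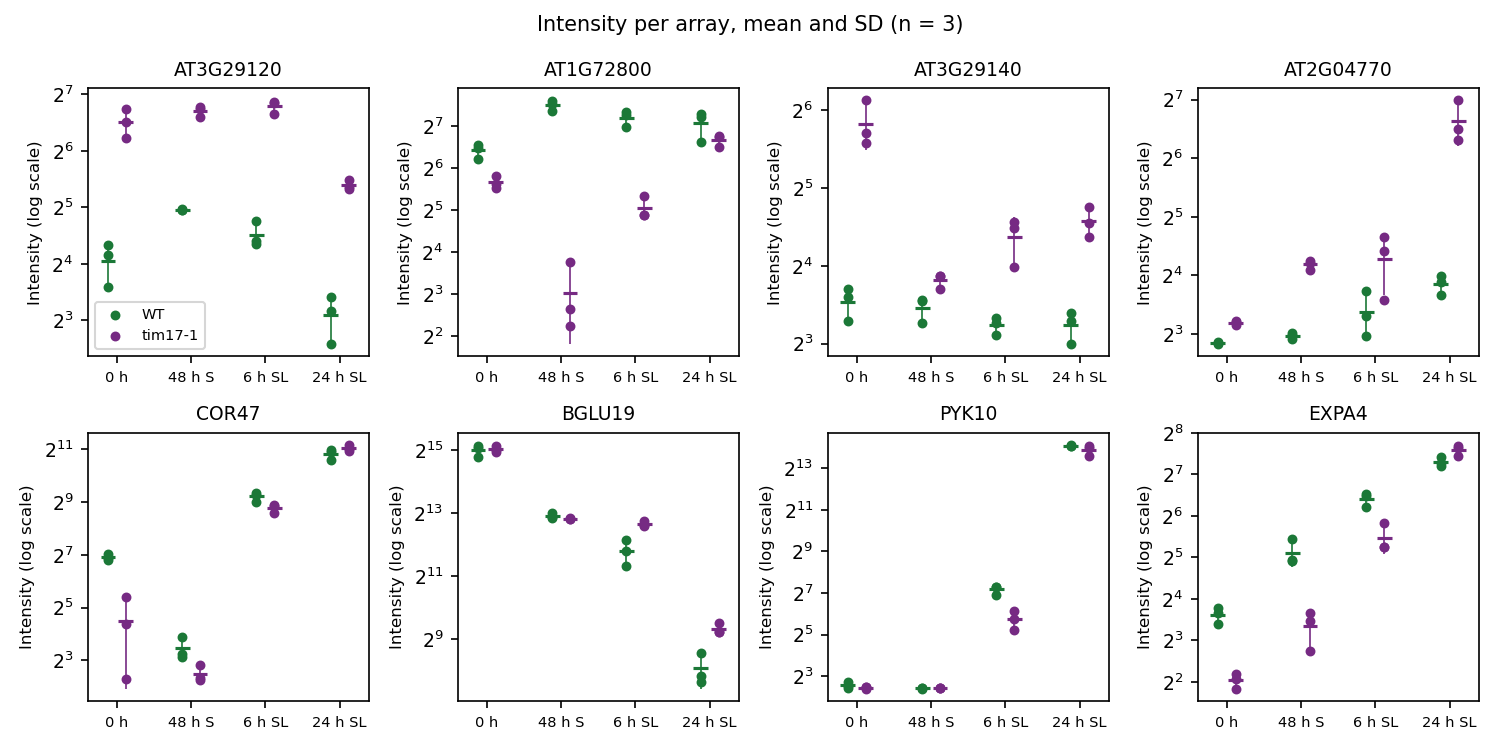
Intensity (y axis, log scale) of 8 genes at the 4 stages (x axis) in WT (green) and tim17-1 (purple), where points are arrays, dashes are means and vertical lines are the SD (n = 3). *AT3G29120* lay higher in tim17-1 at every stage, *AT1G72800* fell to 8.23 in tim17-1 at 48 h S against 180 in WT, and *COR47* lay lower in tim17-1 in dry seed.

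Averaged over the 4 stages, *AT3G29120* was higher in tim17-1 by 1.5 ± 0.0527 (limma, adjusted p = 1.98e-11) and *AT1G72800* lower by a log2 change of -1.42 ± 0.077 (adjusted p = 8.41e-09). The probe set of *AT3G29120* is of a type that can match several transcripts, as is that of *AT2G04770* (0.74 ± 0.0638). *AT3G29140* (0.68 ± 0.0475) and *AT3G20710* (0.51 ± 0.0604) were higher. *AT1G20390* (-0.66 ± 0.0589), *AT1G43590* (-0.66 ± 0.0556), *EXO* (-0.58 ± 0.0602) and *PSAE-1*, a subunit gene of photosystem I (-0.48 ± 0.0693), were lower. *NDB3* (-0.36 ± 0.0689) and *SDH2-1* (-0.18 ± 0.0326) were lower, 1 of 5 alternative pathway and 1 of 10 respiratory chain genes by both counts, and neither list was called (adjusted p = 0.682 for each). Of the 6 LEA genes, *M10* rose (0.22 ± 0.0339), and 2 rose when adjusted over the list alone.

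Of the 4 gibberellin genes, 2 rose by both counts in the average, *SLY1* (0.21 ± 0.0486) and *GID1A* (0.14 ± 0.0351). The gibberellin list (camera, adjusted p = 0.047; adjusted p = 0.139 with an estimated correlation) and the LEA list (adjusted p = 0.0337; adjusted p = 0.333 with an estimated correlation) lay higher. The gibberellin set call was lost without WT 0 h replicate 1 (adjusted p = 0.169), and also, at adjusted p = 0.0505 to 0.0873, without tim17-1 0 h replicate 2, WT 48 h S replicate 3, tim17-1 48 h S replicate 3, WT 6 h SL replicate 2 or 3, tim17-1 6 h SL replicate 3, WT 24 h SL replicate 2 or 3, or any tim17-1 24 h SL array. The LEA set call was lost, at adjusted p = 0.0515 to 0.0754, without WT 0 h replicate 1, tim17-1 0 h replicate 2, WT 48 h S replicate 3, tim17-1 48 h S replicate 1 or 3, WT 6 h SL replicate 1 or 3, WT 24 h SL replicate 2 or tim17-1 24 h SL replicate 1. The *GID1A* call was lost, at 0.12 to 0.14, without WT 0 h replicate 2 or 3, tim17-1 0 h replicate 2, any WT 48 h S array, tim17-1 48 h S replicate 2 or 3, WT 6 h SL replicate 1 or 3, tim17-1 6 h SL replicate 2 or 3, WT 24 h SL replicate 2, or tim17-1 24 h SL replicate 2 or 3.

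Of the 4 import genes, 1 rose in the average, *AT1G50400* (0.19 ± 0.0525, adjusted p = 0.0488), and 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.21). The *AT1G50400* call was lost with cyclic loess (0.18) and, at 0.16 to 0.20, without any 1 array other than tim17-1 0 h replicate 2, WT 48 h S replicate 3, WT 6 h SL replicate 1, WT 24 h SL replicate 3 and tim17-1 24 h SL replicate 1. The cold response gene *COR47* was lower (-0.62 ± 0.117), with 1 member up and 1 down when adjusted over the list alone. The average held 252 higher and 701 lower probe sets, 953 in all. Pollen markers moved with the lower ones, 10 of 21 being lower. Without dry seed, an average chosen after the data were examined, 224 were higher and 555 lower. *AT1G54410* (-0.28), *CCL* (-0.22), *SLY1* (0.16) and *COR47* (-0.18) then no longer passed.

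Calls at different stages were mostly made once: 741 probe sets were higher at 1 stage only and 1328 lower at 1 stage only. *AT3G29120* was higher at all 4 stages. Another probe set, not listed in the annotation and picked after its values were seen, was lower at all 4 (-0.42, -0.93, -1.12 and -0.44). At 6 h SL and 24 h SL, 38 probe sets were higher at both, where independent lists would share 1.85, 31 were lower at both (4.78 for independent lists) and 5 went opposite ways (5.95). At 48 h S and 6 h SL these were 7 (0.418), 18 (1.52) and 5 (1.64). At 48 h S and 24 h SL they were 7 (1.31) and 14 (5.41), with 20 opposite (5.39). Dry seed and 24 h SL shared 12 (4.77) and 33 (14.5), with 8 opposite (16.6). Dry seed shared 3 (1.08) and 10 (4.62) with 48 h S, with 8 opposite (4.53), and 4 (1.53) and 10 (4.09) with 6 h SL, with 2 opposite (5.02).

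From dry seed to 48 h S in WT, the expansin gene *EXPA8* rose from an intensity of 8.87 ± 1.03 (SD, n = 3) to 4418 ± 212 (7.48 ± 0.0727, limma, adjusted p = 4.77e-22) and *XTH19*, a xyloglucan endotransglucosylase gene, from 19.1 ± 0.703 to 5974 ± 341 (7.41 ± 0.112). *AT1G52560*, a small heat shock protein gene, fell from 8167 ± 389 to 30.8 ± 1.66 (-7.45 ± 0.121) and *AT1G54050*, another, from 9711 ± 526 to 83.4 ± 12.1 (-6.62 ± 0.088). *AT3G45310* (7.26 ± 0.0513) rose and *AT2G34740* (-7.23 ± 0.0649) fell. All 4 measured heat shock genes, of 15 listed, fell by both counts, among them *AT1G53540* (-5.76 ± 0.112) and *HSA32* (-3.04 ± 0.114), and the list lay lower (camera, adjusted p = 0.00694; adjusted p = 0.0491 with an estimated correlation). Of the 6 LEA genes, 5 fell, and 5 fell with 1 rising when adjusted over the list alone, among them *AT2G42560* (-4.18 ± 0.146), with no call for the list (adjusted p = 0.0654) except with cyclic loess (adjusted p = 0.000689) or without WT 24 h SL replicate 3 (adjusted p = 0.0452). Of 3 seed storage and oil body genes, 2 fell by both counts, *AT1G03890* (-4.62 ± 0.209) and *OLEO3* (-2.15 ± 0.0905), again with no call for the list (adjusted p = 0.144) except with cyclic loess (adjusted p = 0.026).

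All 4 measured mitochondrial import genes, of 32 listed, rose over this step by both counts, *AT5G05520* (1.27 ± 0.0634) and *AT5G41685* (1.25 ± 0.0898) most. Of 10 respiratory chain genes, 8 rose and 2 fell by both counts, with cytochrome *c* gene *CYTC-1* at 1.95 ± 0.0634, *SDH2-1* at 1.71 ± 0.0652 and *CYTC-2* at -1.31 ± 0.0956. Both lists lay higher as sets, import with adjusted p = 0.0186 and the respiratory chain with adjusted p = 0.00963 (camera; adjusted p = 0.0491 with an estimated correlation for each). Both set calls were lost with cyclic loess scaling (adjusted p = 0.149 and 0.513). Among genes of lists too small to test, *SPT* (3.03 ± 0.0938) and *PRL* (0.66 ± 0.122) rose, and *GI* fell by 1.58 ± 0.103. *ICL*, the isocitrate lyase gene of oil mobilisation, rose by 0.31 ± 0.0844 on the deposited values and lay at -1.25 after cyclic loess, so its direction depends on the scaling. In WT, 6462 probe sets rose and 10163 fell, and the balance turned with cyclic loess (9170 and 7300) and without the dimmest 30% of probe sets (6415 and 5946).

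From 48 h S to 6 h SL in WT, *COR47* rose by 4.50 ± 0.235 (limma, adjusted p = 3.83e-11), *NDB3* by 4.03 ± 0.138 and *DELTA-VPE*, a vacuolar processing enzyme gene, by 4.3 ± 0.197, while *LTI30* fell by 5.02 ± 0.13. *scpl48*, a serine carboxypeptidase-like gene, rose most among the named genes of this step (5.58 ± 0.119), and *AOP3* fell by 4.15 ± 0.135. All 6 LEA genes fell by both counts, with *AT2G42560* at -2.10 ± 0.146 and *M17* at -1.14 ± 0.0934 (camera, adjusted p = 0.00012; adjusted p = 0.0491 with an estimated correlation). Of the 10 respiratory chain genes, 9 rose by both counts, with *SDH2-2* at 1.03 ± 0.104 and *AT3G27240* at 1.02 ± 0.0873 (camera, adjusted p = 0.000675; adjusted p = 0.0223 with an estimated correlation). *PRL* rose by 1.68 ± 0.122 and *XTH33*, a wall-loosening gene, by 0.62 ± 0.146. Over this step 4402 probe sets rose and 4175 fell (4304 and 4387 with cyclic loess).

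From 6 h SL to 24 h SL in WT, *PYK10* rose from 144 ± 21.3 (SD, n = 3) to 17230 ± 417 (6.76 ± 0.134, limma, adjusted p = 3.06e-17), *NAI2*, another gene of endoplasmic reticulum bodies, from 26.3 ± 3.39 to 3747 ± 466 (6.47 ± 0.105), and the jacalin-related lectin gene *JAL34* from 8.62 ± 0.285 to 3185 ± 230 (7.02 ± 0.0535). The LEA genes *M10* (-6.31 ± 0.0678) and *M17* (-4.88 ± 0.0934) and the formate dehydrogenase gene *FDH* (-5.14 ± 0.0882) fell. *PORB* rose by 4.52 ± 0.0698 and *LHCB4.1* by 2.41 ± 0.0723. Of the 6 LEA genes, 4 fell and *LEA4-5* rose (0.79 ± 0.0963), by both counts, with the list lower (camera, adjusted p = 0.0394; adjusted p = 0.397 with an estimated correlation; adjusted p = 0.0778 with cyclic loess). The LEA set call was also lost without tim17-1 6 h SL replicate 1 (adjusted p = 0.0506) or WT 24 h SL replicate 2 (adjusted p = 0.0526). All 4 measured heat shock genes fell by both counts (camera, adjusted p = 0.00963; adjusted p = 0.0491 with an estimated correlation).

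Over the same step all 4 measured import genes fell by both counts, *AT1G50400* most (-2.73 ± 0.105; camera, adjusted p = 0.0118; adjusted p = 0.0491 with an estimated correlation). Of the 10 respiratory chain genes, 7 rose and *CYTC-1* fell (-0.27 ± 0.0634), by both counts, with *SDH1-1* at 0.61 ± 0.0655 (camera, adjusted p = 0.014; adjusted p = 0.0491 with an estimated correlation). *GSTU25* rose by 2.63 ± 0.19. *SDP1*, a lipase gene of oil mobilisation, lay at -0.20 ± 0.0587 on the deposited values and at 0.05 after cyclic loess. In all, 4663 probe sets rose and 5706 fell (5987 and 5790 with cyclic loess).

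**Figure D3:**
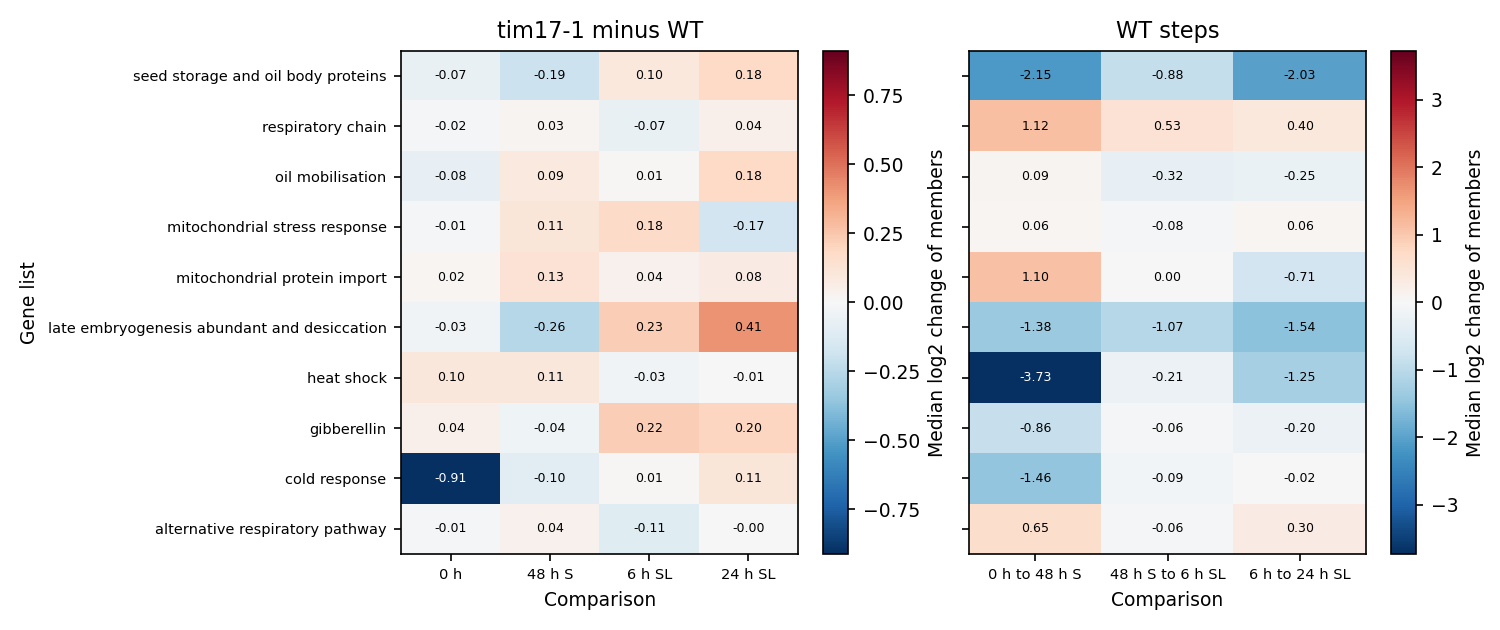
Median log2 change of the measured members (colour and printed value) for the 10 tested gene lists (y axis), as tim17-1 minus WT at each stage (left) and over each WT step (right), with a separate colour scale for each side. The LEA list lies at -0.26 at 48 h S, 0.23 at 6 h SL and 0.41 at 24 h SL, and heat shock genes lie at -3.73 over the first WT step.

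In tim17-1, 6104 probe sets rose and 7482 fell from 0 h to 48 h S, and this balance turned with cyclic loess (8400 and 6501), without the dimmest 30% of probe sets (6108 and 5535) and with only the arrays compared (5774 and 5313). From 48 h S to 6 h SL 4306 rose and 4374 fell (4582 and 4502 with cyclic loess, 5179 and 6956 with array weights). Of these near-equal counts the rising one was also the larger without the dimmest 30% of probe sets (4453 and 4142), with only the arrays compared (4351 and 4019) and with the replicate number as a block (4278 and 4241). It was so without tim17-1 48 h S replicate 1 (3995 and 3966) or 2 (4008 and 3810) and without tim17-1 6 h SL replicate 1 (4025 and 3936), 2 (4065 and 3775) or 3 (4025 and 3682). From 6 h SL to 24 h SL 4705 rose and 5110 fell (5673 and 4671 with cyclic loess). Both genotypes shared 5844 rising and 6592 falling probe sets over the first step, with 20 opposite. They shared 3721 and 3370 over the second, with 15 opposite, and 4087 and 4604 over the third, with 4 opposite.

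The change over the first step differed between genotypes for 610 probe sets, 349 with the larger value in tim17-1 and 261 with the smaller (401 and 147 with cyclic loess). Pollen markers, from the list made after the data were examined, moved with the larger values, 12 of 21 having one. *COR47* was 1 of the 4 cold response genes with a difference (1.63 ± 0.332, limma, adjusted p = 0.0107), and its call was lost with log2(value + 1) (1.95). Adjusted over the list alone, 2 cold response genes differed, and the list was not called (adjusted p = 0.126). *AtLEA4-1* differed by -0.39 ± 0.0745. The counts became 178 and 152 with only the arrays of these groups and 530 and 345 with array weights. They became 414 and 519 without tim17-1 0 h replicate 1, which turned the balance, 279 and 163 and 253 and 144 without WT 48 h S replicate 1 and 2, and 292 and 170 and 272 and 137 without tim17-1 48 h S replicate 1 and 2.

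Over the second step the LEA genes differed as a set, with a median of 0.44 (camera, adjusted p = 1.16e-09; adjusted p = 0.0171 with an estimated correlation). Of the 6, 1 passed over all probe sets, *AtLEA4-1* (0.41 ± 0.0745), and all 6 when adjusted over the list alone. The *AtLEA4-1* call was lost without tim17-1 48 h S replicate 2 (0.40), WT 6 h SL replicate 1 (0.39) or 3 (0.39), or tim17-1 6 h SL replicate 1 (0.38). In all, 163 probe sets differed, 107 with the larger and 56 with the smaller value in tim17-1. The counts were 777 and 934 with array weights, 56 and 62 with only the arrays of these groups, 87 and 37 with log2(value + 1) and 161 and 78 without the dimmest 30% of probe sets. They became 44 and 19 and 55 and 25 without WT 48 h S replicate 1 and 2, 69 and 42 and 39 and 26 without tim17-1 48 h S replicate 1 and 2, 38 and 26, 207 and 96, and 47 and 29 without WT 6 h SL replicate 1, 2 and 3, and 46 and 31, 70 and 39, and 96 and 36 without tim17-1 6 h SL replicate 1, 2 and 3.

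Over the third step the mitochondrial stress response genes differed as a set (camera, adjusted p = 0.00148; adjusted p = 0.0171 with an estimated correlation), with *GSTU25* at -1.52 ± 0.269 (limma, adjusted p = 0.00515) the 1 gene past the test over all probe sets, and 2 past it when adjusted over the list alone. *PORB* differed by -0.59 ± 0.0987 (adjusted p = 0.00284). In all, 349 probe sets differed, 91 with the larger and 258 with the smaller value in tim17-1 (56 and 306 with cyclic loess). The counts became 17 and 45 with only the arrays of these groups, 370 and 460 with array weights, 59 and 286 without WT 24 h SL replicate 1 and 193 and 364 without tim17-1 24 h SL replicate 2.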

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

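The tests of pollen debris, of a single array at 6 h SL or 24 h SL and of RNA quality at 6 h SL, and the look at which arrays a split exchanged, were chosen only after the result was seen. The values below come from a test of the interaction, which asked whether the change over a step differed between genotypes, and are given as tim17-1 minus WT. A larger value in tim17-1 means a larger rise or a smaller fall over the step, and need not be a higher level. Adjacent steps share the arrays of the stage between them, so these tests are not independent. A genotype difference at 1 stage can appear in both steps with opposite signs, as for *AT1G72800* at 48 h S and *PYK10* at 6 h SL.

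From 0 h to 48 h S, 610 probe sets changed differently. *AT2G25450* (2.5), *AT4G16190* (2.05), *AT3G62710* (1.9), *AT4G02250* (1.87) and *AT3G05610* (1.85) had the larger value in tim17-1. *AT1G72800* (-2.42), *AT1G43590* (-1.25), *AT3G29140* (-1.23), *AT4G01897* (-1.1) and *AT2G14060* (-1.08) had the smaller one. Of the former, *AT3G62710*, *AT4G02250* and *AT3G05610* are pollen markers that differed in dry seed (for *AT3G62710* 112 ± 3.03, SD, n = 3, in WT and 20.8 ± 18.1 in tim17-1) and lay low in both genotypes at 48 h S (4.97 ± 0.0656 and 4.98 ± 0.0462), and 12 of the 21 measured markers had the larger value. *AT2G25450* also differed in dry seed (211 ± 68.5 in WT and 23.4 ± 8.29 in tim17-1) and lay low in both genotypes at 48 h S (7.01 ± 0.363 and 7.05 ± 0.351). So did *AT4G16190* (454 ± 104 and 105 ± 51.5, then 7.28 ± 1.14 and 7.55 ± 1.13). The total of 610 became 933 without tim17-1 0 h replicate 1 and 397 without WT 48 h S replicate 2. Of 100 splits of the samples, 1, the real one, gave as many, and the highest of the others gave 517. That split exchanged all 3 tim17-1 arrays with WT at 48 h S and none at 0 h, which turns the difference of the genotype effects into their sum. A chance labelling of these arrays by genotype is argued against. The splits exchanged genotype labels within a stage and so removed the genotype effect itself. They cannot tell whether that effect differed between the 2 stages. Chance between seed lots was not tested, since the arrays of a group may be technical repeats.

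From 48 h S to 6 h SL, 163 probe sets changed differently. *AT1G72800* (1.31), *AT2G29300* (1.26), *AT3G21380* (1.25), *AT2G34315* (1.23) and *AT5G45310* (1.15) had the larger value in tim17-1. *PYK10* (-1.21), *AT4G26790* (-0.822), *ULT1* (-0.815), *AT5G41670* (-0.76) and *AT3G07320* (-0.723) had the smaller one. The call was lost with log2(value + 1) for *AT2G29300* (1.42) and *AT5G45310* (1.20). That of *AT5G45310* was also lost, at 1.02 to 1.14, without WT 48 h S replicate 1, tim17-1 48 h S replicate 2, WT 6 h SL replicate 1 or 3 or tim17-1 6 h SL replicate 1. That of *AT3G07320* was lost, at -0.73 to -0.62, without WT 48 h S replicate 1 or 2, tim17-1 48 h S replicate 2 or tim17-1 6 h SL replicate 1. That of *ULT1* was lost, at -0.85 to -0.74, without any WT 48 h S array, tim17-1 48 h S replicate 1 or 3, WT 6 h SL replicate 1 or 3 or tim17-1 6 h SL replicate 2 or 3. The total became 63 and 80 without WT 48 h S replicate 1 and 2, 65 without tim17-1 48 h S replicate 2, 64, 303 and 76 without WT 6 h SL replicate 1, 2 and 3, and 77 without tim17-1 6 h SL replicate 1. Of 100 splits, 1, the real one, gave as many, and the highest of the others gave 91. A chance labelling of the full set of arrays by genotype is argued against, while chance between seed lots was not tested. As for the first step, these splits cannot tell whether the genotype effect differed between the stages. Several totals without 1 array lay below 91, and no splits were drawn for those fits.

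From 6 h SL to 24 h SL, 349 probe sets changed differently. *AT2G04770* (1.48), *AT1G72800* (1.39), *EXPA4* (1.01), *PYK10* (0.992) and *AT1G71870* (0.982) had the larger value in tim17-1. *GSTU25* (-1.52), *AT5G42760* (-1.41), *AT2G42220* (-1.26), *AT1G48330* (-1.22) and *AT2G27420* (-1.22) had the smaller one. The *AT1G71870* call was lost with log2(value + 1) (1.195) and, at 0.90 to 0.98, without WT 6 h SL replicate 1 or 3, tim17-1 6 h SL replicate 1 or 2, WT 24 h SL replicate 1 or tim17-1 24 h SL replicate 1 or 3. The total became 557 without tim17-1 24 h SL replicate 2. Of 100 splits, 6 gave as many, the real one included, and the highest of the others gave 1011. That split exchanged all 3 tim17-1 arrays with WT at 6 h SL and none at 24 h SL, which turns the difference of the genotype effects into their sum. The structure behind it is the genotype difference itself, and the other 4 splits also kept the arrays of each genotype together at 24 h SL. The splits therefore cannot decide for or against chance here, and chance is not excluded.

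Pollen transcripts were lower in tim17-1 than in WT dry seed. Of 52 listed markers 21 were measured, with *AT3G07820* at 747 ± 82.8 (SD, n = 3) in WT against 223 ± 47 and *AT5G45880* at 680 ± 136 against 205 ± 25.5, and 11 lay over 64 in WT dry seed against 1 in WT at 24 h SL. The median of the 21 was -1.27 after cyclic loess and at most -1.07 without any 1 of the 6 arrays. Since 8 of the 21 were genes already seen to be lower in these arrays, this median cannot decide on normalization or a single array. Neither check was run on the other 13 alone. Some markers also lay above their later level in tim17-1 dry seed, as *AT3G07820* (223 against 6.03 at 48 h S) and *AT5G45880* (205 against 5.63). Pollen or flower debris in dry seed, more of it in the WT samples, may be the source. The 13 markers not among the genes already seen had a median of -0.258, with 12 negative and 6 called lower. Some of the 12 were weak in both genotypes, as *AT3G07840* at 3.35 in WT and 3.34 in tim17-1 dry seed. The median lay at percentile 0 among 10000 random lists of the same size and level. Level was the mean over all 24 arrays, so markers high only in dry seed were set against genes that may be weak there. That percentile cannot tell debris from other sources. A difference of the mutant's own seed transcripts stays open, untested, as does the time since harvest, which the labels word differently for the genotypes.

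At 6 h SL, tim17-1 lay behind WT along the time course: the 200 genes that rose most in WT from 48 h S to 24 h SL had a median of -0.218 in tim17-1 against WT and the 200 that fell most 0.311, a difference of -0.529, with 175 and 181 of them on that side. Normalization and a single array are argued against, since the difference was -0.514 after cyclic loess and -0.465 or further from 0 without any 1 array. An RNA quality difference in both the actin and GAPDH controls is argued against, since only 1 of them had separate arrays, GAPDH (-0.01 ± 0.068 against -0.16 ± 0.0443), while a difference that touches some transcripts stays open. A slower start in tim17-1 at 6 h SL is a hypothesis, and the differences at 0 h (-0.0294) and 48 h S (0.0547, the other way), on genes of other steps, had overlapping arrays. Whether tim17-1 lay behind at 24 h SL stays open. The genes tested there, those of the step from 48 h S to 6 h SL, need not still be changing. They gave -0.038 with overlapping arrays (-0.0432 after cyclic loess, -0.0273 nearest to 0 without 1 array). Of the actin and GAPDH controls, 0 had separate arrays there. On the first component tim17-1 at 24 h SL lay apart from WT, toward 6 h SL (93.4 to 94.06 against 98.19 to 101.2). The LEA list, which fell over the last WT step, was higher in tim17-1. The photosynthesis list, made after the data were examined, rose over it and was lower. The heat shock and respiratory chain lists also changed over it but were not called between genotypes. None of these was a test of a lag.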

How the results depend on the processing

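The average without dry seed was chosen only after the result was seen. The cause was not tested unless a sentence names it. Of 4548 alternative values of 274 changes of named genes, 322 lost their call and 2 reversed, both after cyclic loess: *ICL* in WT from 0 h to 48 h S, at -1.254, and *SDP1* in WT from 6 h SL to 24 h SL, at 0.05226. With only the arrays of the groups compared, limma called 39 probe sets at 0 h, 178 at 48 h S, 0 at 6 h SL (2165 at an unadjusted p under 0.05) and 4 at 24 h SL, and 330 for the interaction of the first step and 62 for that of the last. Such a fit has fewer residual degrees of freedom and takes the spread from those groups alone. Which of these lowered the counts was not tested. With array weights the counts were 459 at 0 h, 4106 at 48 h S, 847 at 6 h SL, and 1711 and 830 for the interactions of the steps to 6 h SL and to 24 h SL. With only probe sets of 1 gene, hence fewer tested, they were 404, 139, 134 and 445 at the 4 stages, 391 in the average, 9881, 4550 and 5698 for the WT steps, 7843, 4724 and 5359 for the tim17-1 steps, and 253, 84 and 142 for the interactions. With log2(value + 1), 193 were called at 6 h SL. Calls of gene lists went from 29 to 17 with an estimated correlation. All set calls given above for lists fixed beforehand, in tim17-1 against WT at a stage or in the average, were among those lost. Without 1 array the counts ranged from 744 to 1176 at 0 h, 101 to 485 at 48 h S, 140 to 315 at 6 h SL, 647 to 1274 at 24 h SL and 746 to 1120 in the average. They ranged from 15028 to 16554, 7920 to 8107 and 9613 to 9878 for the WT steps, 12252 to 14019, 7707 to 8822 and 9156 to 9264 for the tim17-1 steps, 397 to 933, 63 to 303 and 254 to 557 for the interactions, and 25 to 33 for gene lists. The arrays that moved a total, or its higher or lower part, by over 1.5 times stand beside the counts above. All other alternatives run for these totals (cyclic loess, the filter on dim probe sets, the trended and robust prior) stayed within 1.5 times. With the replicate number as a replicate block the counts were 794, 246, 269 and 956 at the stages, 946 in the average and 553, 116 and 349 for the interactions. Of 12 same-numbered pairs, 1 had a correlation over 0.1 (range -0.306 to 0.16) and 2 were best with their own number, so the numbers do not pair samples. Without dry seed the average gave 779. The fit over only the groups compared was not run for the average, which uses all groups. Signal over background was not measured here and limits weak transcripts.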

Other observations

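The gene lists below and the test of chance in the neighbourhood of *TIM17-1* were chosen only after the result was seen. The lists contain genes already seen, so they are not independent evidence.

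At 24 h SL, 9 of 28 nuclear genes of photosynthesis were lower in tim17-1 and 14 when adjusted over the list alone, among them *PSAE-1* (-1.02 ± 0.139, limma, adjusted p = 0.000171), the calcium sensor gene *CaS* (-0.98 ± 0.128) and the phosphoribulokinase gene *PRK* (-0.71 ± 0.104). The list was lower (camera, adjusted p = 3.68e-16; adjusted p = 0.00148 with an estimated correlation), and its change from 6 h SL to 24 h SL differed between genotypes (adjusted p = 4.98e-09; adjusted p = 0.0168 with an estimated correlation). In WT 27 of the 28 rose over that step, with a median of 2.03. In dry seed, 5 of 16 genes of the mitochondrial genome were lower in tim17-1 and 6 when adjusted over the list alone, with *ccb206* at -0.55 ± 0.0551, *nad6* at -0.47 ± 0.0885 and *nad9* at -0.46 ± 0.0857 (camera, adjusted p = 1.96e-06; adjusted p = 0.0117 with an estimated correlation). At that stage the pollen markers were lower too (median -1.27), and the 3' to 5' log2 difference of the ubiquitin control was -0.21 ± 0.0265 (SD, n = 3) in WT and -0.34 ± 0.0614 in tim17-1. Of the mitochondrial genes, *cox2* was lower at 0 h (-0.35 ± 0.0726), 6 h SL (-0.51 ± 0.0726) and 24 h SL (-0.30 ± 0.0726), the last not without WT 24 h SL replicate 1 (-0.30) or 2 (-0.24) or tim17-1 24 h SL replicate 2 (-0.25) or 3 (-0.31). All 16 fell in WT from 0 h to 48 h S, *cox2* most among those named (-4.36 ± 0.0726). The LEA family differed over the step from 48 h S to 6 h SL, with 6 of 36 larger in tim17-1 and 19 when adjusted over the list alone (camera, adjusted p = 1.97e-15; adjusted p = 0.0236 with an estimated correlation).

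Of 21 pollen markers, 14 were lower in tim17-1 dry seed and 17 when adjusted over the list alone (camera, adjusted p = 3.79e-33; adjusted p = 0.00148 with an estimated correlation). Of 10 genes of endoplasmic reticulum bodies, 6 rose and *BGLU19* fell (-3.66 ± 0.192) in WT from 6 h SL to 24 h SL (camera, adjusted p = 0.000454; adjusted p = 0.0389 with an estimated correlation). Of 10 small heat shock genes, 8 fell and *AT4G21870* rose (3.42 ± 0.179) in WT from 0 h to 48 h S (camera, adjusted p = 0.000674; adjusted p = 0.0265 with an estimated correlation). Of 9 oleosin, caleosin and cupin genes, 8 fell over that step (camera, adjusted p = 0.00214; adjusted p = 0.268 with an estimated correlation). Of 69 plastid genome genes, 1 was lower in tim17-1 at 48 h S and 6 when adjusted over the list alone (camera, adjusted p = 1.22e-14; adjusted p = 0.127 with an estimated correlation). Of 28 expansin and xyloglucan endotransglucosylase genes, 3 were lower in tim17-1 at 48 h S, and the list was not called (adjusted p = 0.941), with a median (0.0066) of another sign than its mean (-0.06) and test. Of 16 pentatricopeptide repeat factors, 8 rose in WT from 0 h to 48 h S (camera, adjusted p = 0.00929; adjusted p = 0.0714 with an estimated correlation).

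Of the 20 measured genes nearest to *TIM17-1*, 10 on each side and at -21 to 22 annotated genes from it, 2 were lower in the average over stages, *AT1G20390* (-0.66), 8 genes away, and *COR47* (-0.62), 14 genes away. By stage, *AT1G20390* lay at -0.64, -0.396, -0.756 and -0.849, called at all but 48 h S. *COR47* lay at -1.95, -0.313, -0.427 and 0.211, called only at 0 h. A fall shared by the measured neighbours was not seen: their median was -0.0015, and 16.9% of 13083 windows of 20 genes elsewhere had one as low. The nearest measured genes lay at -4 and 5 annotated genes from *TIM17-1*, and the offset understates changes of weak transcripts. The median therefore cannot exclude an effect that spreads over the neighbourhood. Chance may account for the count, since 14.8% of those windows held as many called genes. An effect on these 2 genes alone was not tested.

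For each comparison of 3 with 3 arrays the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many probe sets. At 0 h the real split gave 831 and the highest other 309, at 48 h S 280 and 41, at 6 h SL 291 and 3, and at 24 h SL 983 and 284. For the WT steps these were 16625 and 2, 8577 and 1, and 10369 and 2, and for the tim17-1 steps 13586 and 6, 8680 and 1, and 9815 and 0. For the average over stages, 1 of 100 splits, the real one, gave 953, and the highest other gave 307. A chance labelling of these arrays is argued against, while chance between seed lots was not tested.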
